A study of Danio rerio with 44 samples.

How the data were processed

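RNA was sequenced from 44 pools of 20 whole zebrafish embryos, each pool exposed for 72 h to PFOS, PFECHS or FBSA at 4 concentrations or to the solvent alone. The series provides a table with a column per library and a line for each of 25859 Ensembl gene identifiers. The deposited values are taken to be expected counts, that is, estimated counts of reads per gene that need not be whole numbers. This unit was settled from the values themselves: none is negative, between 54.1% and 79.8% of a library's values are not whole, and totals differ between libraries. Reads were checked with FastQC and MultiQC and trimmed with Trimmomatic, per the submitters' processing notes. The program that made the estimates and the genome build are not given in the sources used here, so no coordinates are printed. Every column was mapped to a sample by its group and replicate number, and 0 columns were left without a sample.

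Groups were taken from the sample labels: 3 compounds, each with a solvent control and 4 concentrations, giving 15 groups. No measured value was used to place a library. The deposited counts were rounded to whole numbers, and genes with too few counts were removed with edgeR's filterByExpr by group, which left 22703 genes. At the depth of these libraries 1 count equals between 0.0274 and 0.0409 CPM. Gene symbols came from a name table for 23598 of the identifiers, and 3608 identifiers share their symbol with another, so identifiers are printed beside such symbols. The capitals of many symbols are those of that table.

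Differential expression was tested in R 4.3.3 with edgeR 4.0.16 (TMM factors, quasi-likelihood F test) in a single fit over all 44 libraries, with 29 residual degrees of freedom and a common dispersion of 0.068. The contrasts were each concentration against the compound's own controls (12), a linear trend with equal steps from control to 5 mg/L for each compound (3), the difference in change between each pair of compounds at each concentration (12) and the controls of each pair of series (3). Adjusted p-values are Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Standard errors are the size of the log2 fold change divided by the root of the F statistic. The FBSA libraries spread more within groups (median standard deviation 0.386 in log2 CPM) than those of PFOS (0.255) and PFECHS (0.252), while the single fit shares its estimate of spread across compounds.

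The 42 gene lists, the tests and the rule for naming genes were fixed before the data were examined. Lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2, at its preset correlation between genes, for lists with at least 5 members tested. Adjustment ran over all lists and the 12 concentration contrasts together, and the differences between compounds formed their own family. List members are also counted by their edgeR calls, over all genes and adjusted over the list alone. Of the 1359 symbols in the lists, 986 were found under the same symbol, 65 by a synonym in the RefSeq table of assembly GRCz12tu, which was used for names only, 216 by the symbol without its copy letter or number and 92 not at all. The third kind of match can bring in each copy of a duplicated gene.

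Genes were named by rank of fold change at 5 mg/L: the 8 called genes furthest up and the 8 furthest down whose exposed and control pools did not overlap and whose mean log2 CPM was at least 1. The first 3 in each direction were named elsewhere, by p for trends and without the overlap condition for differences, and up to 3 members with the smallest p in a list. A set of indicator genes was named whatever its result. Some genes that these rules would name are not reported here. Where fewer than 6 genes were called every called gene with a symbol was named. Symbols that hold a colon or a clone prefix with 4 or more digits were taken as placeholders and left unnamed. The 3 called PFOS genes with a placeholder or no symbol were added after their values were seen.

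Correlations of fold changes between compounds used differences in mean log2 CPM over all genes tested. Their p-values come from every relabelling of exposed and control libraries within each compound, 400 relabellings or 200 where FBSA at 0.1 mg/L takes part. The shared part of correlations between concentrations of a compound was estimated from 20 simulated sets without an effect. Principal components were computed on log2 CPM.

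The calculation was tested on simulated data drawn from the genes' mean levels, the library totals and the fitted dispersions, without the larger axes of variation between libraries. For FBSA at 5 mg/L it called 15 of 67 genes changed 1.5-fold, 37 of 67 changed 2-fold and 64 of 66 changed 4-fold, and it called 5 genes that had not been changed, out of 22703 genes in all. With nothing changed, the comparison of PFOS at 5 mg/L called 0 genes. A list lowered 1.5-fold in the simulation was called and none of 40 unchanged lists was. Effects of 2-fold or less are therefore often missed with 3 pools per group. The simulated spread is the one shared over all compounds, while the FBSA libraries spread more, so these shares can be too high for FBSA.

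Alternatives fixed in advance were DESeq2 size factors within edgeR, the Wald test of DESeq2 1.42.0, no low-count filter, a fit of only the compounds compared (for differences only the groups in the contrast, for controls only the control groups), the replicate number as a block, and leaving out each library in turn. For lists they were a correlation estimated for each list, the self-contained rotation test fry, the block and the compound's own libraries. For correlations they were a prior count of 0.5, genes with a mean log2 CPM of at least 3, and leaving out each library. Added after seeing the data were a term for the last 11 libraries of the table, the first 33 libraries alone, a term for the main axis between libraries with and without restriction to the compounds compared, and lists matched by the same symbol only. The main-axis term was the first component of the PFOS and PFECHS libraries, with the FBSA libraries projected on it. Its correlation with component 1 of all libraries was 0.977. Printed positions on the main axis are component 1 of all libraries, which was also the term in the main-axis test of cell cycle genes under PFOS. Per-list results under the alternatives are printed for 5 mg/L and for FBSA at 1 mg/L. That choice was made after a first version covering every concentration had shown many lists turning direction, and totals over every called list are given in the closing part.

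Replicate numbers were checked for pairing across groups: libraries of a compound with the same number correlated after group means were removed by 0.015 for PFOS, -0.035 for PFECHS and 0.084 for FBSA on average. The numbers were therefore not used as pairs in the tests reported. No library was left out. Identifiers below the filter, vtg1 among them, were not tested, and FBSA at 0.1 mg/L has 2 libraries, which lowers the power of every comparison that uses it.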

Results

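Gene expression was measured by RNA sequencing in whole wild-type zebrafish embryos held from 24 to 96 hours after fertilization in 1 of 3 fluorinated compounds. PFOS is perfluorooctane sulphonate, the long-used member of the family. PFECHS is perfluoroethylcyclohexane sulphonate, which carries a ring in place of the straight chain, and FBSA is perfluorobutane sulphonamide, with a shorter chain and an amide head. Each compound was given at 5, 1, 0.1 or 0.001 mg/L in 0.1% DMSO, and each had its own solvent controls. The question set for the series was how sub-lethal concentrations, including those met in the environment, act on the transcriptome. The data held 44 libraries in 15 groups, with 3 libraries per group except FBSA at 0.1 mg/L, which had 2. Each library was a pool of 20 embryos, so p-values measure the spread between these pools and not between single fish. In every comparison 22703 genes were tested. Gene symbols are given as the annotation table has them, in capitals where it uses the human-style name.

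In the FBSA 5 mg/L pools the lists for the eye lens, exocrine pancreas, intestine, sterol synthesis and cell cycle were lower than in the controls, and the p53 and glucocorticoid lists were higher, by camera at its preset correlation. None of these 7 calls held with a correlation estimated for each list (adjusted p = 0.855 for lens and 0.936 for the others). Fry, which asks only whether a list's genes change at all, called lens and cell cycle (adjusted p = 0.00300 and 0.0107) but not the rest. In all, 1314 genes rose and 1236 fell, 793 of these 2550 by at least 2-fold (edgeR quasi-likelihood, Benjamini-Hochberg 0.05, n = 3 against 3). Among genes with a usable symbol and a mean log2 CPM of at least 1, the largest increases with no overlap between exposed and control pools were in SLC16A9 (ENSDARG00000013926, a monocarboxylate transporter family member), gh1 (growth hormone), ATF3 (a stress-induced transcription factor), ARRDC3 (an arrestin-domain protein), CYP24A1 (vitamin D breakdown), c4b and c6.1 (complement) and FOSL1 (an AP-1 subunit). Their log2 fold changes ran from 2.33 to 2.65. ATF3 (ENSDARG00000007823) rose by 2.54 ± 0.42 (SE) on the log2 scale, adjusted p = 0.000553, and ARRDC3 (ENSDARG00000036028) by 2.45 ± 0.40, adjusted p = 0.000474. By the same rule the largest decreases were in ctrb.2, ela2 and ela2l (digestive proteases), apoa4b.3 (an apolipoprotein), cyp2n13 (a cytochrome P450), chia.2 (a chitinase), PRKG2 (a cGMP-dependent kinase) and ANPEP (ENSDARG00000103878, a brush-border peptidase), with log2 fold changes from -3.42 to -2.87. The largest of these, ctrb.2 (ENSDARG00000093844), fell by 3.42 ± 0.93, adjusted p = 0.0182. With only the FBSA libraries in the fit the count was 0, with 3548 genes at an unadjusted p under 0.05. It was 452 without control replicate 2, 141 without 5 mg/L replicate 3 and 5197 without 5 mg/L replicate 2. Of the control pools 2 of 3 are among the last 11 libraries of the table, and of the 5 mg/L pools 0. Exposure and table place are therefore partly confounded in this comparison. With table place as a term the called genes' fold changes had a median ratio of 0.894 to those without it.

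**Figure D1:**
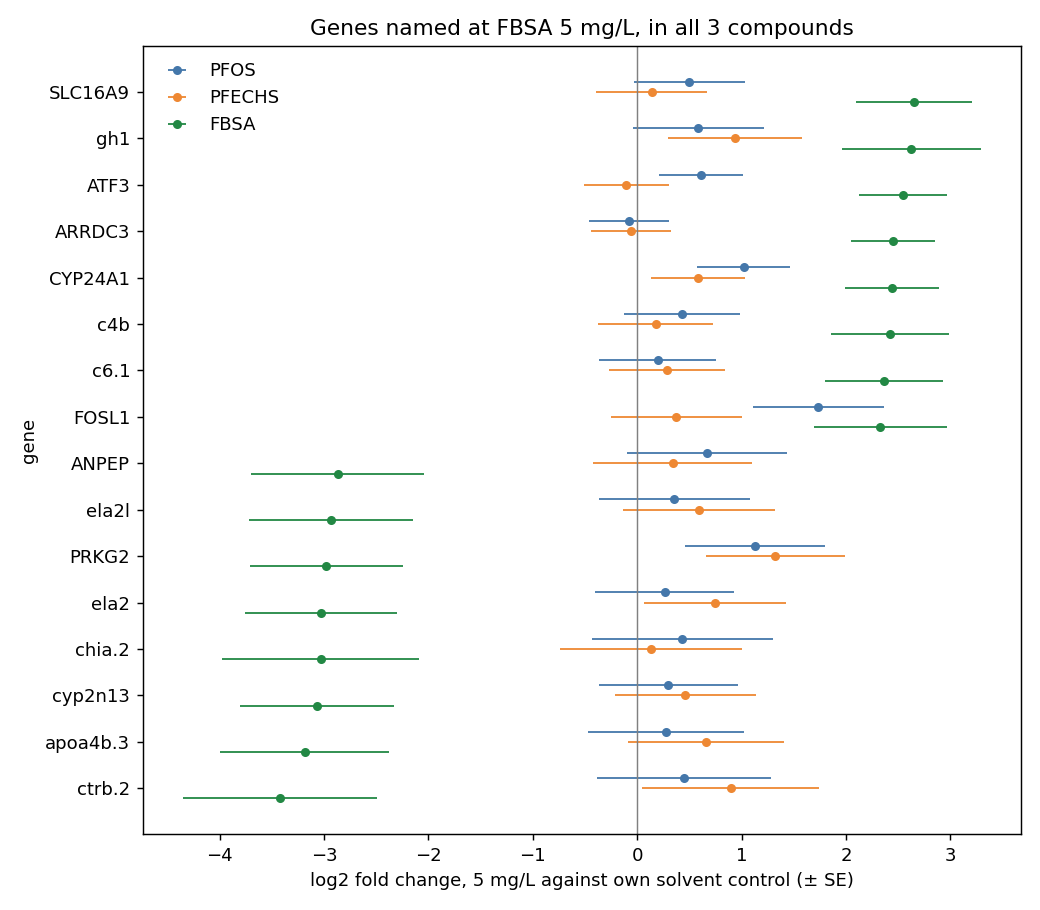
Log2 fold change against the compound's own solvent control (x axis) at 5 mg/L for the 16 genes named for FBSA (y axis), with points coloured by compound and bars of 1 standard error. The 8 genes named for their rises under FBSA lie between 2.33 and 2.65 and the 8 named for their falls between -3.42 and -2.87.

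The lens list had the largest share of its members called. Of 44 lens genes measured at FBSA 5 mg/L, 36 fell over all genes tested and 39 adjusted over the list alone, none rose, and the median log2 fold change was -1.38. The structural crystallins crygm2d8 (-1.73 ± 0.25), crygm2d9 (-2.03 ± 0.31) and crygm2d11 (-1.62 ± 0.25) each had an adjusted p = 0.000345. Members of the crygm2d family are near-identical copies that can share reads, so the value of any single copy is uncertain. The list mean of log2 CPM was 5.64, 5.96 and 5.48 in the exposed pools against 7.41, 7.19 and 6.54 in the controls. The camera test gave an adjusted p = 1.8e-29, and adjusted p = 0.855 with an estimated correlation between genes. Fry gave an adjusted p = 0.00300, though it asks only whether the list's genes change at all. In the retina, 7 of 46 phototransduction genes fell (11 adjusted over the list alone), among them the cone channel subunit CNGA3 (ENSDARG00000070726, -1.25 ± 0.34), with a list median of -0.64, camera adjusted p = 1.5e-05 and adjusted p = 0.936 with an estimated correlation. The fall was in 2 of the 3 pools: the list means were 6.45, 4.92 and 4.94 against 5.89, 5.78 and 6.59 in the controls, so exposed replicate 1 lay above 2 controls.

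Digestive organ genes fell as groups. In the exocrine pancreas list 12 of 26 genes fell (19 adjusted over the list alone; median -1.67), including the amylase amy2al2 (-2.54 ± 0.60) and the elastase ela2 (-3.03 ± 0.73). In the intestine list 9 of 36 fell and 1 rose (18 and 1 adjusted over the list alone; median -1.62): the retinol-binding RBP2 (ENSDARG00000070038) fell by 1.39 ± 0.33, ANPEP fell by 2.87 ± 0.83 and the endocytic adaptor DAB2 rose by 0.74 ± 0.18. The intestine list means overlapped: exposed replicate 2 (2.67) lay above control replicate 3, while controls 1 and 2 stood at 4.24 and 3.99. Among xenobiotic metabolism genes 7 of 38 fell (16 alone; median -1.17), such as cyp2n13 (-3.07 ± 0.73) and the glutathione transferase gsta.1 (-1.22 ± 0.30). Lipoprotein genes fell in 5 of 23 cases (10 lower and 1 higher alone; median -1.26), among them apoea (-2.42 ± 0.60) and apoa4b.2 (-2.81 ± 0.71). Liver markers had a median of -0.77 with 2 of 35 called (1 alone), including the clotting regulator PROC (ENSDARG00000093079, -1.68 ± 0.38), and bile acid genes a median of -0.78 with 1 of 21 called (1 alone), the ileal binding protein FABP6 (-2.31 ± 0.69). All 6 lists were called lower by camera, with an adjusted p of 9.2e-08 for exocrine pancreas, 4.4e-06 for intestine, 5.3e-05 for xenobiotic metabolism, 0.0012 for lipoproteins, 0.0257 for liver and 0.046 for bile acids. For each of them adjusted p = 0.936 with an estimated correlation. These lists also vary along the main axis between libraries, on which control replicates 1 and 2 (48.8 and 54.3) lay apart from control replicate 3 (-67.3) and from 5 mg/L replicates 1 and 3 (-65.9 and -66.9). With the main-axis term, chosen after seeing the data, 3606 genes were called at FBSA 5 mg/L. Of the 6 lists, exocrine pancreas and intestine were still called with the term, xenobiotic metabolism (adjusted p = 0.218), lipoproteins (0.152) and bile acids (0.835) were not, and the liver list turned direction (0.477). With the FBSA libraries alone, a planned setting, bile acids were not called by camera (0.0655). With lists matched by the same symbol liver was not (0.124).

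Sterol synthesis genes fell in 12 of 26 cases (13 adjusted over the list alone; median -0.63), led by lanosterol synthase LSS (-1.41 ± 0.25, adjusted p = 0.00109) and squalene synthase FDFT1 (-1.36 ± 0.26, adjusted p = 0.00182). In the cell cycle list 18 of 47 genes fell (22 lower and 1 higher alone; median -0.33), including the nuclear import adaptor KPNA2 (-0.77 ± 0.12), the topoisomerase TOP2A (-0.71 ± 0.14) and the replication helicase subunit MCM3 (-0.68 ± 0.14). Proteasome genes were lower by a median of -0.18 with 6 of 39 called (15 alone), for example PSMD4 (-0.41 ± 0.11). Nuclear genes of oxidative phosphorylation had a median of -0.20 with 5 of 82 called (3 alone). Camera gave an adjusted p of 1.6e-06 for sterol synthesis, 1.3e-07 for the cell cycle, 0.00013 for the proteasome and 4.8e-06 for oxidative phosphorylation, all with adjusted p = 0.936 with an estimated correlation. By fry the cell cycle had an adjusted p = 0.0107, and sterol synthesis, the proteasome and oxidative phosphorylation were not called. Skeletal muscle (44 genes, median -0.49, camera adjusted p = 0.00027), cardiac muscle (27, -0.32, 0.041) and erythrocytes (20, -0.50, 0.0337) were also lower as lists. They had 1, 1 and 2 called members, the erythrocyte pair being the transcription factor klf1 (-2.43 ± 0.57) and the embryonic globin hbae3 (-0.83 ± 0.24). Adjusted over the list alone 0, 0 and 3 members were lower, and adjusted p = 0.936 with an estimated correlation for each. With the main axis as a term none of these 3 lists was called: skeletal muscle had an adjusted p = 0.477, erythrocytes 0.508, and cardiac muscle turned direction (0.878). Cardiac muscle was not called by camera with the FBSA libraries alone (0.0544) or with lists matched by the same symbol (0.242).

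The p53 and glucocorticoid lists were higher at FBSA 5 mg/L, while the heat shock, unfolded protein response and antioxidant lists had negative medians and were not called. In the p53 list 5 of 20 genes rose (7 higher and 1 lower alone; median 0.31), among them the pro-apoptotic bbc3 (1.38 ± 0.27), SESN1 (1.00 ± 0.21) and PHLDA3 (0.85 ± 0.20). In the glucocorticoid and stress list 6 of 24 rose (9 alone; median 0.53): SOCS3 (ENSDARG00000026611), a feedback inhibitor of cytokine signalling, rose by 1.29 ± 0.27, the pituitary precursor POMC by 2.73 ± 0.63 and the glucocorticoid receptor NR3C1 by 0.50 ± 0.13. Mitochondrially encoded genes had a median of 0.17 with 1 of 13 called (2 alone), MT-CO2 (0.45 ± 0.13), and ribosomal protein genes a median of 0.24 with 0 of 76 called by edgeR over all genes and 0 alone. Camera gave an adjusted p of 0.00093 for p53, 0.00055 for glucocorticoid, 0.0404 for the mitochondrial genome and 3.9e-07 for ribosomal proteins, and adjusted p = 0.936 with an estimated correlation for each. The glucocorticoid list was not called with the table-place term (camera adjusted p = 0.0567) or the first 33 libraries. The mitochondrial genome was not called with these (0.133 with table place) or the main axis (0.0545). These settings were chosen after seeing the data. In the planned setting with the FBSA libraries alone the mitochondrial genome was not called either (0.0724). Several lists held called genes without being called themselves. The glucose transporter SLC2A1 (ENSDARG00000001437) of the glycolysis list had the smallest p of all genes tested (-1.93 ± 0.26, adjusted p = 0.000345, a value shared by several genes). The endoplasmic reticulum chaperones HSPA5 (-0.62 ± 0.13) and HSP90B1 (-0.85 ± 0.20) fell while ATF3 of the same list rose. The myelin genes mag (-1.62 ± 0.36) and dhrs12la (-1.19 ± 0.24) fell, and the pineal melatonin enzyme aanat2 (1.79 ± 0.43), the clock regulator rorcb (1.02 ± 0.24), the peroxidase gpx3 (1.70 ± 0.37), the thyrotropin-releasing hormone gene TRH (0.92 ± 0.22) and the complement protease MASP1 (1.11 ± 0.25) rose.

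**Figure D2:**
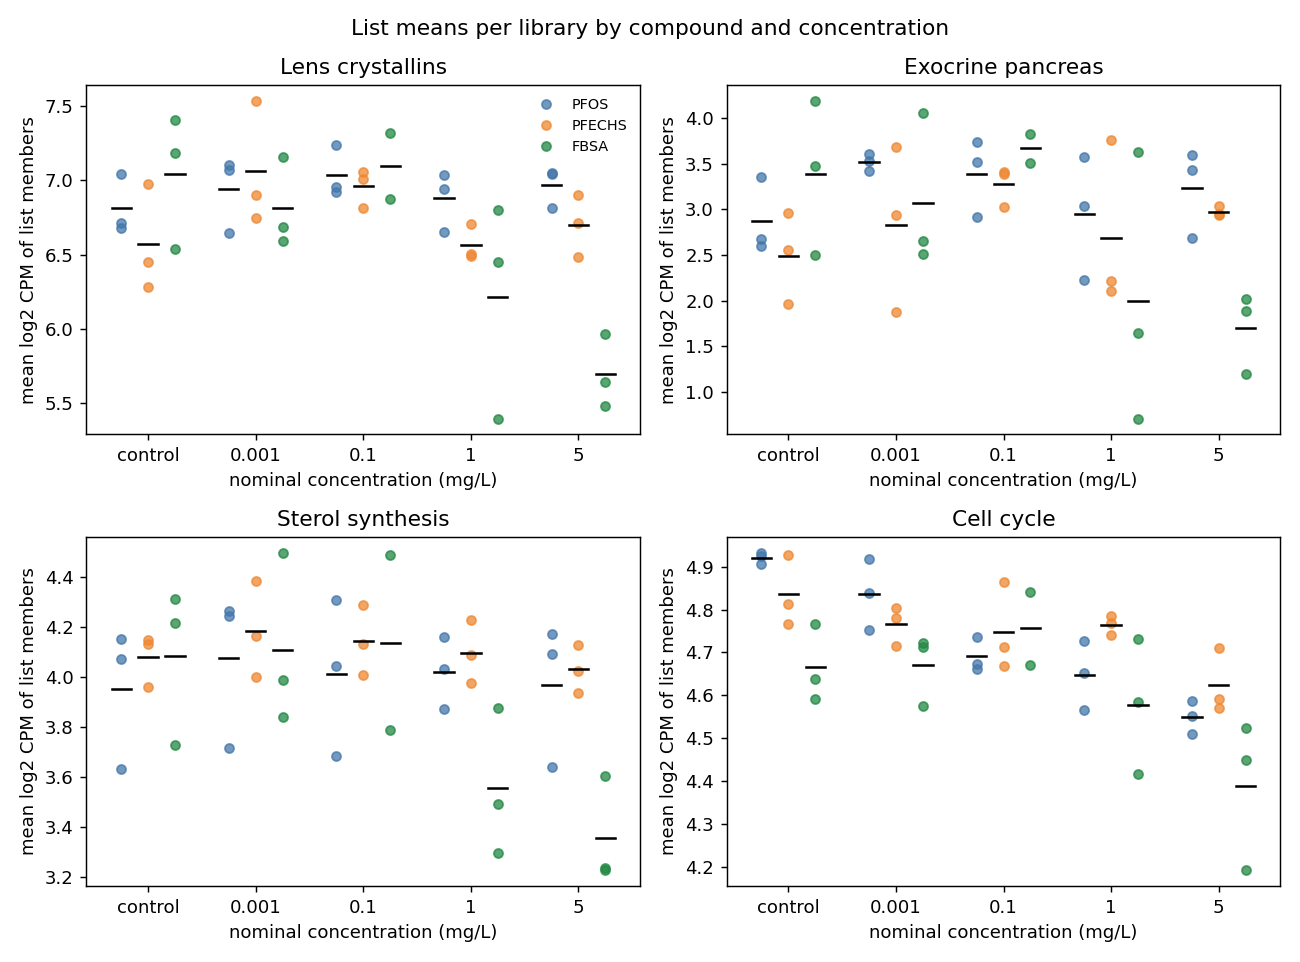
Mean log2 CPM (y axis) of the lens, sterol synthesis, exocrine pancreas and cell cycle lists in each library, by compound and concentration in mg/L (x axis); dots are libraries and bars are group means. In the lens list the FBSA 5 mg/L pools lie at 5.64, 5.96 and 5.48, below the FBSA control pools at 7.41, 7.19 and 6.54.

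The lists not called at FBSA 5 mg/L are given with their median log2 fold change and the members called higher and lower over all genes. They were fatty acid oxidation (-0.22; 0 and 2 of 40), fatty acid synthesis (-0.13; 0 and 2 of 19), aryl hydrocarbon receptor targets (-0.11; 0 and 0 of 15), Nrf2 targets (-0.20; 2 and 3 of 25), antioxidant enzymes (-0.16; 1 and 1 of 17), the unfolded protein response (-0.09; 3 and 6 of 23), heat shock (-0.17; 2 and 3 of 22) and glycolysis (-0.20; 0 and 2 of 40). Next came the thyroid axis (0.21; 4 and 1 of 17), steroid and estrogen genes (-0.14; 0 and 2 of 18), the circadian clock (0.06; 6 and 2 of 32), neurons (0.18; 2 and 1 of 38), glia and myelin (0.01; 2 and 4 of 23) and endocrine pancreas (0.60; 1 and 1 of 16). The rest were myeloid cells (0.28; 2 and 0 of 32), complement (-0.05; 3 and 0 of 37), interferon response (0.24; 1 and 1 of 25), cartilage and bone (0.26; 0 and 0 of 34), extracellular matrix (0.02; 2 and 0 of 39), keratins (-0.13; 0 and 3 of 38), ionocytes and kidney (-0.13; 2 and 4 of 41), swim bladder (0.18; 2 and 0 of 11) and hatching gland (0.21; 2 and 0 of 12). Adjusted over the list alone, endocrine pancreas had 5 higher and 1 lower and glia 4 and 7, and the aryl hydrocarbon receptor, cartilage and extracellular matrix lists had 0. Endocrine pancreas, not called by camera, was called higher by fry (adjusted p = 0.0241). The mean and the test were lower for glia (mean -0.17) where the median was above 0. For complement (mean -0.16) the median and mean were below 0 where the test pointed up, and for extracellular matrix the mean was -0.04 with the median and test up.

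At FBSA 1 mg/L no gene was called, and most lists called lower at 5 mg/L had negative medians too, with skeletal muscle (0.008) an exception and the proteasome at -0.05. Both concentrations are set against the same 3 controls, so part of this likeness is built in, and it was not tested. Camera called 0 lists higher at 1 mg/L, against 4 at 5 mg/L. Of the 44 lens genes 43 had a negative fold change at 1 mg/L, with a median of -0.78 and 29 lower adjusted over the list alone. All 26 sterol synthesis genes were below the controls, with a median of -0.48 and 8 lower alone. The medians were -1.15 for intestine (2 lower alone), -0.97 for exocrine pancreas (0), -0.74 for xenobiotic metabolism (4) and -0.62 for phototransduction (0). These lists were among 16 called lower by camera at 1 mg/L, with adjusted p = 0.515 for lens, 0.892 for sterol synthesis and 0.936 for the others with an estimated correlation. The pools overlapped: replicate 3 at 1 mg/L lay above control replicate 3 in the lens (6.80 against 6.54), sterol (3.88 against 3.73) and intestine lists, and in exocrine pancreas (3.63) above control replicates 1 (3.48) and 3. In phototransduction replicates 2 and 3 (5.82 and 5.89) lay above control replicate 2 (5.78). Over all genes edgeR called 0 at 0.001, 0.1 and 1 mg/L, where 259, 731 and 1499 genes had an unadjusted p under 0.05 and DESeq2 called 0, 0 and 35. Without replicate 3 at 1 mg/L edgeR called 89 genes there.

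Across the control and all 4 FBSA concentrations, 1274 genes were called higher and 1264 lower by the linear trend contrast per concentration step. The contrast weighs the control and 5 mg/L pools most, so a gene changed only at 5 mg/L can be called. Whether genes change steadily over the steps was not tested. Among genes with a usable symbol, the smallest p for a rise were in the phosphatase CTDSPL (0.19 ± 0.03 log2 per step), the actin-branching subunit ARPC5 (0.18 ± 0.03) and the tight-junction claudin cldn7a (0.40 ± 0.06), and for a fall in SLC2A1 (-0.49 ± 0.06) and the spectrin sptbn5 (-0.50 ± 0.06). Each of these 5 had an adjusted p of 7.5e-05 or less. By list, 39 of 44 lens genes, 18 of 46 phototransduction genes, 18 of 47 cell cycle genes, 16 of 36 intestine genes, 14 of 38 xenobiotic metabolism genes, 13 of 26 sterol synthesis genes and 13 of 26 exocrine pancreas genes fell along the trend, and 39, 25, 24, 26, 20, 15 and 22 did adjusted over the list alone. In the intestine list 1 gene rose by either count. The trend count was 0 with only the FBSA libraries in the fit, 474 without 5 mg/L replicate 3, 1074 without control replicate 2 and 4561 without 5 mg/L replicate 2. It was 3986 with the main axis between libraries as a term. The trend uses the same control and 5 mg/L pools, so its partial confounding with table place is the same.

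Few single genes were called under PFOS by edgeR in the fit of all libraries, and more in other settings given below. Cell cycle genes were lower as a group by camera at its preset correlation. Of the 47 cell cycle genes, 44 were below the controls at 5 mg/L, with a median log2 fold change of -0.36. None was called over all genes by edgeR, and 24 were lower adjusted over the list alone, led by the mitotic activator CDC20 (-0.49 ± 0.11), the kinase plk1 (-0.50 ± 0.12) and the cyclin CCNA2 (-0.49 ± 0.12). Camera gave an adjusted p = 5.7e-26, and adjusted p = 0.0954 with an estimated correlation. Fry gave an adjusted p = 0.00488. Along the PFOS trend 5 cell cycle genes fell over all genes tested, and 30 adjusted over the list alone. Proteasome genes were lower by a median of -0.21 (37 of 39 negative, camera adjusted p = 3.0e-14, adjusted p = 0.892 with an estimated correlation; 14 lower along the trend alone).

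Of single genes, PFOS raised COLGALT1 (ENSDARG00000058270, a collagen-modifying glycosyltransferase) by 1.23 ± 0.21 at 0.1 mg/L, adjusted p = 0.0137, and vwa7 (ENSDARG00000061462) by 1.14 ± 0.21, adjusted p = 0.0351. At 1 mg/L it lowered GINS3 (ENSDARG00000038847), a subunit of the replicative helicase, by a log2 fold change of -0.88 ± 0.16, adjusted p = 0.0383. At 5 mg/L it raised RGCC (ENSDARG00000035810), a cell cycle regulator, by 1.09 ± 0.20, adjusted p = 0.0379. The other called genes have no usable symbol and were named after their values were seen. They were si:dkey-27m7.4 (ENSDARG00000003146), higher at 0.1, 1 and 5 mg/L by 3.13 ± 0.48, 2.76 ± 0.48 and 2.81 ± 0.48, ENSDARG00000110040 at 0.1 mg/L (3.37 ± 0.60) and si:dkey-175g6.2 (ENSDARG00000086665) at 5 mg/L (1.83 ± 0.33). The counts were thus 0, 4, 2 and 3 from 0.001 to 5 mg/L (edgeR, n = 3 against 3), with 1537, 3431, 1790 and 1812 genes at an unadjusted p under 0.05 and 1, 46, 27 and 98 by DESeq2. Of the 3 counts above 0, the one at 0.1 mg/L was 376 and the one at 5 mg/L 40 with the PFOS libraries alone. At 0.1 mg/L it was 0 without control replicate 2, 1 without control replicate 1 or 3 or exposed replicate 1 or 3, and at 5 mg/L 0 without control replicate 2 or 3 or exposed replicate 1, 1 without control replicate 1 and 5 without exposed replicate 2. At 1 mg/L it was 1 without control replicate 1 and 0 without any other of the 6 libraries. The fit of all libraries shares its spread with the FBSA libraries, which spread more within groups (0.386 against 0.255 for PFOS). Its counts can therefore be too low for PFOS, which was not tested.

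By the PFOS trend contrast 48 genes were higher and 31 lower, and here too a steady change over the steps was not tested. The neuropeptide precursor vgf rose by 0.31 ± 0.05 log2 per step (adjusted p = 0.00252), RGCC by 0.28 ± 0.04 and COLGALT1 by 0.26 ± 0.05, and GINS3 (-0.20 ± 0.03), the RNA polymerase III subunit POLR3K (-0.17 ± 0.03) and CDC20 (-0.13 ± 0.02, adjusted p = 0.0187) fell. DESeq2 called 250 genes. The count was 119 with the PFOS libraries alone and, in settings chosen after seeing the data, 299 with the table-place term, 313 with the main axis, 281 with the PFOS libraries alone and the axis, and 232 in the first 33 libraries. The trend count was 5 to 13 without control replicates 1, 2 or 3 (5, 12 and 13), 7 without 5 mg/L replicate 1, 19 without 1 mg/L replicate 2, and 25 to 43 without 7 others: 32, 25 and 42 without 0.001 mg/L replicates 1 to 3, 37 without 0.1 mg/L replicate 1, 38 without 1 mg/L replicate 1, and 28 and 43 without 5 mg/L replicates 2 and 3.

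Extracellular matrix, cardiac and cartilage genes were higher as lists under PFOS and PFECHS at 5 mg/L, also with the main axis as a term, with no member called over all genes by edgeR. For PFOS all 39 extracellular matrix genes were above the controls (median 0.67, camera adjusted p = 1.0e-09), as were 26 of 27 cardiac genes (median 0.68, 2 higher alone; MYH6 0.71 ± 0.21) and 31 of 34 cartilage genes (median 0.53, 2 higher alone; the matrix protein gene MATN1 1.48 ± 0.41). With an estimated correlation none of these 3 lists was called for either compound (adjusted p = 0.936 for each). With the main axis as a term, extracellular matrix and cartilage were called higher under FBSA at 5 mg/L too (camera adjusted p = 5.5e-07 and 0.00013). Without that term they were not called under FBSA (0.922 and 0.585). Further medians under PFOS were 0.49 for myeloid cells, 0.46 for glucocorticoid genes, 0.44 for xenobiotic metabolism, 0.43 for complement, 0.42 for liver and 0.40 for the thyroid axis. For these lists an estimated correlation gave an adjusted p = 0.515 for the thyroid axis and 0.936 for the rest. Fry called the thyroid axis (adjusted p = 0.0107) and not the rest. With the main axis as a term the liver and xenobiotic lists turned direction, and complement (adjusted p = 0.997) and myeloid cells (0.331) were not called. With lists matched by the same symbol the thyroid axis was not called (camera adjusted p = 0.0946). In the neuron list, not called, the neurofilament genes nefma (0.97 ± 0.20), nefmb (0.90 ± 0.19) and nefla (0.72 ± 0.20) were higher adjusted over the list alone. Camera called 17 lists higher and 6 lower at 0.001 mg/L of PFOS, 11 and 5 at 0.1 mg/L, 10 and 3 at 1 mg/L, and 16 and 3 at 5 mg/L, and with an estimated correlation it called 0 in each.

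PFECHS gave no called gene at any concentration or along its trend. Of 47 cell cycle genes, 45 were below the controls at 5 mg/L (median -0.22, 1 lower alone, camera adjusted p = 1.7e-10, adjusted p = 0.855 with an estimated correlation), with CDC20 at -0.56 ± 0.11 (adjusted p = 0.387). The proteasome (36 of 39 negative, median -0.19, camera adjusted p = 7.6e-11), oxidative phosphorylation (69 of 82 negative, -0.10, 0.00013) and the unfolded protein response (17 of 23 negative, -0.13, 0.0363) were also lower as lists, each with adjusted p = 0.936 with an estimated correlation. All 39 extracellular matrix genes were above them (median 0.61), as were 32 of 35 liver genes (0.78), 25 of 27 cardiac genes (0.63), 32 of 34 cartilage genes (0.59, 2 higher alone) and 31 of 37 complement genes (0.65), each with adjusted p = 0.936 with an estimated correlation. With the main axis as a term the liver (adjusted p = 0.749) and complement (0.831) lists were not called. The unfolded protein response was not called with the table-place term (camera adjusted p = 0.156) or the first 33 libraries (0.140). MATN1 stood at 1.56 ± 0.42 (adjusted p = 0.704). Camera called 12 lists higher and 4 lower at 0.001 mg/L, 15 and 4 at 0.1 mg/L, 11 and 3 at 1 mg/L and 10 and 4 at 5 mg/L, and with an estimated correlation it called 0 in each. The edgeR count of 0 stood beside 856, 844, 425 and 1597 genes at an unadjusted p under 0.05 from the lowest to the highest concentration, and 773 for the trend. DESeq2 called 1, 2, 1 and 3 genes at the 4 concentrations and 0 for the trend.

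The 3 compounds share a fluorinated backbone and differ in chain or ring and head group, and they were compared at matched mass concentrations by testing the difference between their changes. The change under PFOS at 5 mg/L differed from that under FBSA in 1116 genes (523 higher under PFOS, 593 lower), and the change under PFECHS differed from that under FBSA in 2081 (1093 and 988). Among genes with a usable symbol, the differences that led each list were GLS2 (glutaminase; PFOS minus FBSA 4.40 ± 1.23, PFECHS minus FBSA 3.96 ± 1.24), PRKG2 (4.11 ± 0.99 and 4.30 ± 0.99), the photoreceptor gene rp1l1b (PFOS minus FBSA 3.68 ± 0.99, but 3.18 ± 1.11 and not called with the replicate block, adjusted p = 0.0745) and ctrb.2 (PFECHS minus FBSA 4.32 ± 1.25) on the higher side. On the lower side were ARRDC3 (-2.53 ± 0.55 and -2.51 ± 0.55), ATF3 (PFECHS minus FBSA -2.65 ± 0.58), the pituitary hormone subunit CGA (PFOS minus FBSA -2.17 ± 0.61) and SLC16A9, whose symbol covers ENSDARG00000104687 (PFOS minus FBSA -2.19 ± 0.54) and ENSDARG00000013926 (PFECHS minus FBSA -2.52 ± 0.76). In settings chosen after seeing the data other calls were lost as well. With the main-axis term GLS2 went to 2.03 and 1.87, ctrb.2 to 2.05 and CGA to -2.08, none of them called. With the table-place term rp1l1b, CGA and both SLC16A9 genes were not called. Lens genes differed by a median of 1.46 for PFOS minus FBSA and 1.51 for PFECHS minus FBSA, exocrine pancreas genes by 2.26 and 2.19 and sterol synthesis genes by 0.52 and 0.42. Cell cycle genes differed by -0.04 and 0.13. Both counts were 0 in a fit of only the control and 5 mg/L libraries of the pair. That fit leaves out the other concentrations and keeps fewer residual degrees of freedom than the fit of all libraries.

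The PFOS minus FBSA count at 5 mg/L was 56 without FBSA 5 mg/L replicate 3, 77 without FBSA control replicate 2, 2613 without FBSA control replicate 3 and 4100 without FBSA 5 mg/L replicate 2. It was 220 and 540 without PFOS 5 mg/L replicates 3 and 1, and 362, 281 and 754 without PFOS control replicates 1, 2 and 3, the last within 1.5 times of 1116. PFECHS minus FBSA was 333 without FBSA 5 mg/L replicate 3, 362 and 3400 without FBSA control replicates 2 and 3, and 4917 without FBSA 5 mg/L replicate 2. It was 674 and 1068 without PFECHS 5 mg/L replicates 3 and 2, and 1174 and 1003 without PFECHS control replicates 1 and 2. Of the PFOS minus FBSA calls 46.9% were higher under PFOS, against 37.8% with DESeq2 size factors in edgeR.

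PFOS and PFECHS, the pair of sulphonates, were not told apart in any gene by edgeR, while DESeq2 called 1 or 2 genes at each concentration. At 5 mg/L the difference in COLGALT1 was 0.34 (95% interval -0.25 to 0.93), in CDC20 0.07 (-0.25 to 0.38) and in ARRDC3 -0.02 (-1.11 to 1.08). Before adjustment the interval excluded 0 for si:dkey-27m7.4 (1.90, 0.59 to 3.21), si:dkey-175g6.2 (1.85, 0.93 to 2.77), vgf (1.18, 0.57 to 1.80), RGCC (0.84, 0.27 to 1.41) and GINS3 (-0.53, -0.98 to -0.08), among the genes followed for PFOS, with an adjusted p = 1.00 for each. The median interval reached 0.73 log2 to either side of the estimate, a factor of 1.66. Differences of that size between the pair remain open, and larger ones where the estimate lies away from 0 or the interval is wider. By edgeR 0 genes differed at each of the 4 concentrations, with 215, 317, 292 and 241 genes at an unadjusted p under 0.05 and 1, 2, 1 and 1 by DESeq2. At 5 mg/L the glucocorticoid list (0.48), p53 list (0.18), neurons (0.11), glycolysis (0.14) and oxidative phosphorylation (0.09) were higher and the cell cycle (-0.13) lower under PFOS than under PFECHS by camera on the differences. None of the 6 was called with an estimated correlation.

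Below 5 mg/L no gene differed between FBSA and either sulphonate by edgeR. For PFOS minus FBSA 1104, 1128 and 1876 genes had an unadjusted p under 0.05 at 0.001, 0.1 and 1 mg/L and DESeq2 called 2, 0 and 17. For PFECHS minus FBSA the numbers were 681, 467 and 783, and 0, 0 and 1 by DESeq2. Fold changes across genes correlated between PFOS and PFECHS with Pearson's r of 0.47, 0.52, 0.31 and 0.44 from the lowest to the highest concentration (Spearman's coefficient 0.54, 0.59, 0.42 and 0.55). Exact permutation of library labels, two-sided, gave p of 0.03, 0.01, 0.14 and 0.01 and, over the 12 correlations computed, adjusted p of 0.12, 0.06, 0.336 and 0.06, where 0.01 is the smallest p these labels allow. On the main axis the PFOS controls (-22.9, -42.6 and -0.03) and PFECHS controls (-17.8, -37.2 and -62.7) lay below most of their exposed pools. No correlation was computed with that axis removed, so these values are not read as a shared response to the compounds. Between PFOS and FBSA r was -0.30, 0.33, -0.06 and -0.22 (adjusted p 0.427, 0.427, 0.807 and 0.427), and between PFECHS and FBSA -0.20, 0.34, 0.02 and -0.37 (adjusted p 0.804, 0.42, 0.88 and 0.24). Genes are not independent replicates, and within a compound fold changes share control libraries. At 1 and 5 mg/L r was 0.74 for PFOS, 0.54 for PFECHS and 0.58 for FBSA, against 0.50, 0.50 and 0.49 in 20 simulations with no effect. The simulations use a spread shared across compounds and leave out the main axis, on which the FBSA controls lie far apart, so the value without an effect can be too low for FBSA and no excess is read from it.

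The solvent controls of the 3 series were compared as a check of the groups. Between PFOS and FBSA controls 17 genes were higher and 17 lower, among them the dynein light chain DNAL4 (1.23 ± 0.26), the transcription repressor DR1 (0.83 ± 0.17) and krcp (0.71 ± 0.15) higher in PFOS controls, and fam83ga (-2.02 ± 0.37), the chaperone CLPB (-1.57 ± 0.34) and the mitochondrial carrier SLC25A42 (-1.49 ± 0.31) lower. By edgeR 0 genes differed between PFOS and PFECHS controls (229 at an unadjusted p under 0.05, 1 by DESeq2) and 0 between PFECHS and FBSA controls (5185 and 1317). The count of 34 was 0 with only the control libraries, 0 with the place in the deposited table as a term (chosen after seeing the data) and 597 by DESeq2. It was 271 and 84 without FBSA control replicates 1 and 3, 0 without FBSA control replicate 2, and 1, 0 and 0 without PFOS control replicates 1, 2 and 3. The PFECHS and FBSA control count was 511 and 1653 without FBSA control replicates 1 and 3.

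**Figure D3:**
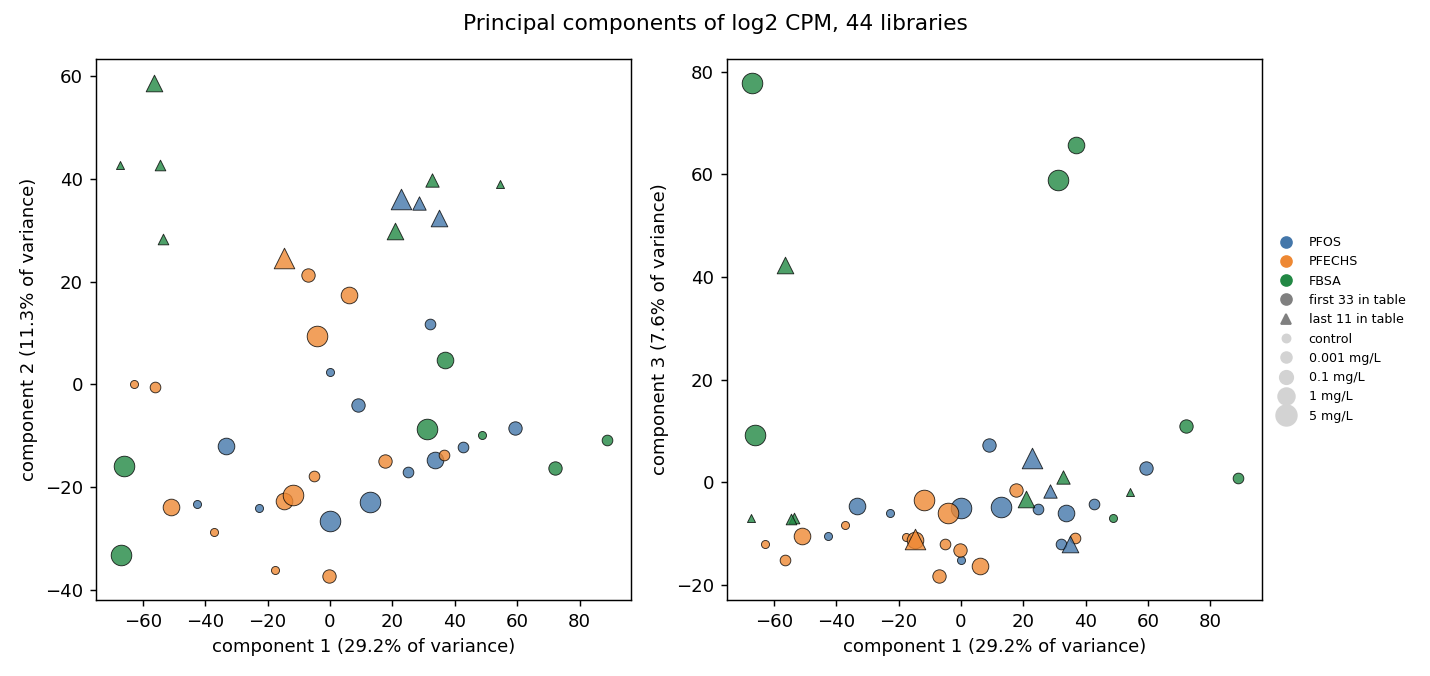
Principal components 1, 2 and 3 of log2 CPM, which hold 29.2%, 11.3% and 7.6% of the variance, with a point per library coloured by compound; triangles are the 11 libraries that come last in the deposited table. Those 11 lie at 24.7 to 58.7 on component 2 and the other 33 at 21.3 or below.

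Indicator genes fixed in advance showed little. Of the genes for fatty acid binding, pyruvate dehydrogenase kinase, heme oxygenase, aromatase, cytochrome P450 and the clock, only FABP1 (ENSDARG00000059227) was called at 5 mg/L, lower under FBSA (-2.67 ± 0.64, adjusted p = 0.00846). The dioxin-responsive CYP1A1 stood at 0.50 ± 0.63, 0.20 ± 0.63 and -0.69 ± 0.63 under PFOS, PFECHS and FBSA, cyp3a65 at 1.06 ± 0.72, 0.61 ± 0.72 and -2.18 ± 0.75 (adjusted p = 0.0533 under FBSA), and PDK2 (ENSDARG00000059054) at 1.88 ± 0.67, 0.81 ± 0.65 and 0.36 ± 0.65. With the main axis as a term CYP1A1 stood at -0.13, -0.43 and 0.33, each on the other side of 0. The egg-yolk gene vtg1 had 33.7 counts over all libraries and was not tested.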

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

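The table-place, first-33 and shared-spread tests and the settings with the main axis were chosen after seeing the data, while the splits of the libraries were planned. What brought these results here is a test of whether the change at 5 mg/L differs between 2 compounds. The change differed from that under FBSA in 1116 genes for PFOS and in 2081 for PFECHS. Among genes with a usable symbol, those that led PFOS minus FBSA were GLS2 (4.40), PRKG2 (4.11), rp1l1b (3.68), ARRDC3 (-2.53), SLC16A9 (ENSDARG00000104687, -2.19) and CGA (-2.17). By the same rule those that led PFECHS minus FBSA were ctrb.2 (4.32), PRKG2 (4.30), GLS2 (3.96), ATF3 (-2.65), SLC16A9 (ENSDARG00000013926, -2.52) and ARRDC3 (-2.51).

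In each of these genes the part under FBSA was the larger. GLS2 stood at -3.02 ± 0.90 under FBSA, 1.38 ± 0.84 under PFOS and 0.94 ± 0.86 under PFECHS, and PRKG2 at -2.98 ± 0.73, 1.13 ± 0.67 and 1.32 ± 0.67. ARRDC3 stood at 2.45 ± 0.40, -0.08 ± 0.38 and -0.06 ± 0.38, ATF3 at 2.54 ± 0.42, 0.61 ± 0.40 and -0.10 ± 0.40, and CGA, the subunit shared by the pituitary glycoprotein hormones, at 2.32 ± 0.45, 0.15 ± 0.43 and 0.45 ± 0.44.

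The main axis between libraries carried part of this, unequally across genes. With the axis as a term the difference in ctrb.2 (PFECHS minus FBSA) went from 4.32 ± 1.25 to 2.05 ± 0.94 (adjusted p = 0.158) and GLS2 from 4.40 ± 1.23 to 2.03 ± 0.64 (PFOS, adjusted p = 0.0603) and from 3.96 ± 1.24 to 1.87 ± 0.64 (PFECHS, adjusted p = 0.0595). These calls ended because the fold became smaller, and the digestive genes along the axis may be the source. PRKG2 went to 4.96 ± 0.98 (PFOS) and 5.19 ± 0.98 (PFECHS), rp1l1b to 4.86 ± 0.93, ARRDC3 to -2.59 ± 0.58 and -2.56 ± 0.58, ATF3 to -2.60 ± 0.61, and both SLC16A9 genes to -1.94 ± 0.56 and -2.88 ± 0.81, all still called with this term. CGA went from -2.17 ± 0.61 to -2.08 ± 0.65 (adjusted p = 0.0571), with nearly the same fold and spread. With table place as a term instead, rp1l1b went to 2.59 ± 0.93 (adjusted p = 0.0799), SLC16A9 ENSDARG00000104687 to -1.60 ± 0.51 (0.0553), SLC16A9 ENSDARG00000013926 to -1.52 ± 0.67 (0.127) and CGA to -2.09 ± 0.66 (0.0542), none of them called. The fold became smaller in the first 3, while CGA changed little. With the replicate block rp1l1b went to 3.18 ± 1.11 (adjusted p = 0.0745), with a smaller fold and a larger spread. With the first 33 libraries, where FBSA keeps 1 control, PRKG2 (PFOS) and ATF3 were called and the other 10 differences were not. Among these were ARRDC3 at -2.64 ± 0.69 and -2.39 ± 0.68 (adjusted p = 0.0565 and 0.0847), PRKG2 at 3.69 ± 0.93 (PFECHS, 0.0766), the SLC16A9 genes (0.0801 and 0.120) and CGA at -1.74 ± 0.91 (0.262). With only the control and 5 mg/L groups of the 2 compounds in the fit none of the 12 was called (adjusted p from 0.109 to 0.189). The folds barely moved, for example GLS2 4.39 ± 1.14 (PFOS), ARRDC3 -2.54 ± 0.55 (PFOS), ctrb.2 4.32 ± 0.76 and ATF3 -2.64 ± 0.44. That fit keeps fewer residual degrees of freedom, which can end calls as well. In ctrb.2, ATF3 and GLS2 (PFOS) the standard error fell, so this loss does not speak against those differences.

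Of the 1116 genes 478 were among the 974 called with the main-axis term, and of the 2081 genes 1119 were among 1984.

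Among the 2550 genes called at FBSA 5 mg/L, from which these differences come, the first or last place in the table and the main axis were each tested as the whole cause. The median ratio of fold changes with the term to without was 0.894 for table place (0.846 to 0.919 with a library left out) and 0.870 for the main axis (0.780 to 0.924), where a cause would have brought it below 0.5. The spread is a different matter: with the FBSA libraries alone the genes' standard errors were 1.27 times as large (median), and edgeR called 0, with 2435 of 2548 at an unadjusted p under 0.05 and a smallest adjusted p of 0.167 (median fold 0.747 against 0.745 on the log2 scale, median standard error 0.248 against 0.201). DESeq2 called 3505 in the fit of all libraries and was not run on the FBSA libraries alone. An effect of FBSA, the biological explanation the design gives, stays open beside a count raised by the borrowed spread, and both are hypotheses. The fit of the FBSA libraries alone also keeps fewer residual degrees of freedom than the 29 of the fit of all libraries. Its count of 0 can come from that as well as from the larger standard errors, and these were not told apart.

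Other splits of the same libraries show how strong the axis is. For FBSA at 5 mg/L 10 splits are too few for a share under 0.05. The real count was 2550 and the highest other 6989, so 2 of the 10 gave as many. That highest split sets control replicates 1 and 2 and exposed replicate 2 against the rest, which is the order along the main axis (48.8, 54.3 and 31.1 against -67.3, -65.9 and -66.9). This structure of the samples crosses the exposure labels but is partly aligned with them. Whether it is unrelated to exposure was not tested, and a term for it can also take away part of an exposure effect. For PFOS minus FBSA 2 of 25 splits gave as many as 1116 (highest other 3005), and for PFECHS minus FBSA 2 of 25 gave as many as 2081 (highest other 4303), so chance is not excluded for either. In both highest splits FBSA 5 mg/L replicates 1 and 3 and control replicate 3 stand together. The first 33 libraries alone, all in the earlier part of the table, gave 253 and 33 genes, of which 119 and 28 were among the 1116 and 2081. With a library left out the counts lay between 56 (without FBSA 5 mg/L replicate 3) and 4100 (without FBSA 5 mg/L replicate 2) for PFOS minus FBSA and between 333 and 4917 (the same libraries) for PFECHS minus FBSA, and the report names each library that moves them.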

How the results depend on the processing

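The table-place term, the first 33 libraries, the main-axis term (with or without only the compounds compared) and the matching of lists by the same symbol were tests chosen after seeing the data. The lens, sterol and digestive changes under FBSA rest on 3 exposed and 3 control pools and on a spread shared with PFOS and PFECHS libraries. No independent series was at hand, the cause of the changes between settings was not tested except where stated, and read mapping, gene models and sequencing depth could not be varied because only a count table is deposited. All alternatives fixed in advance were run, apart from the replicate block for the controls, with which it is confounded.

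With only the compounds compared in the fit, no gene was called by edgeR at FBSA 5 mg/L (0, against 2550; 3548 genes at an unadjusted p under 0.05 and 3505 called by DESeq2 in the fit of all libraries). The FBSA trend, PFOS minus FBSA at 5 mg/L, PFECHS minus FBSA at 5 mg/L and the PFOS against FBSA controls also fell to 0. For differences this setting kept only the groups in the contrast, and for controls only the control groups. The same setting gave 376 genes at PFOS 0.1 mg/L, 40 at PFOS 5 mg/L, 119 in the PFOS trend and 1 in PFOS minus FBSA at 1 mg/L. The other 21 counts of 30 stayed within 1.5 times.

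The DESeq2 Wald test gave more genes in 24 of 30 counts and the same number in 6, and in these 21 the change was over 1.5 times: PFOS 1, 46, 27 and 98 from 0.001 to 5 mg/L and 250 in the trend, PFECHS 1, 2, 1 and 3, and FBSA 35 at 1 mg/L. It gave PFOS minus FBSA 2 at 0.001, 17 at 1 and 2319 at 5 mg/L, PFECHS minus FBSA 1 at 1 mg/L, PFOS minus PFECHS 1, 2, 1 and 1, and for the controls 597 (PFOS and FBSA), 1317 (PFECHS and FBSA) and 1 (PFOS and PFECHS). Without the low-count filter PFOS 1 mg/L fell to 0, and the other 29 counts stayed within 1.5 times. DESeq2 size factors left all 30 counts within that range, and the replicate block left all 27 it was run for.

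With the table-place term the counts were 7, 5 and 92 at PFOS 0.1, 1 and 5 mg/L, 299 in the PFOS trend and 0 for the PFOS against FBSA controls. CYP19A1 at PFECHS 5 mg/L turned to -0.30 and PDK2 (ENSDARG00000059054) at FBSA 5 mg/L to -0.59, neither called. Among lists at FBSA 5 mg/L cartilage (adjusted p = 0.567), complement (0.688) and extracellular matrix (0.188) turned direction.

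With only the first 33 libraries, the FBSA control, 0.001, 0.1 and 1 mg/L groups keep 1 library each, assumed to vary like the other groups, so counts below 5 mg/L set 1 FBSA library against 1 and say nothing about stability. FBSA 5 mg/L gave 408 genes, PFOS minus FBSA 253 and PFECHS minus FBSA 33 at 5 mg/L. FBSA at 0.001, 0.1 and 1 mg/L gave 2, 1 and 1, PFOS minus FBSA 1, 1 and 1 and PFECHS minus FBSA 2, 1 and 1. PFOS gave 2, 0 and 60 at 0.1, 1 and 5 mg/L and 232 in the trend, and the PFOS against FBSA and PFECHS against FBSA controls 1 each. The lists called at FBSA 0.001 mg/L rose to 24. CYP19A1 at PFECHS 5 mg/L turned to -0.34, HMOX1 at PFOS 5 mg/L to -0.28, the complement gene c4 at PFOS 1 mg/L to -0.047 and cyp1c1 at FBSA 5 mg/L to -0.047. The lists cartilage (adjusted p = 0.407), complement (0.578) and extracellular matrix (0.105) turned at FBSA 5 mg/L.

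With the main-axis term the counts were 9 at FBSA 1 mg/L, 3986 in the FBSA trend, 1, 0 and 19 at PFOS 0.1, 1 and 5 mg/L, 313 in the PFOS trend, 11 in PFOS minus FBSA at 1 mg/L and 228 for the PFOS against FBSA controls. Indicator genes that were not called turned: CYP1A1 to 0.33 (FBSA), -0.43 (PFECHS) and -0.13 (PFOS), CYP19A1 to 0.019 and HMOX1 to -0.45 (PFOS), FABP1 (ENSDARG00000059227) to -0.084 and cyp3a65 to -0.073 (PFECHS), all at 5 mg/L. Camera then called 7 lists at PFOS 0.001 mg/L, 11 at PFOS 5 mg/L and 12 at PFECHS 0.1 mg/L. At FBSA 5 mg/L these lists turned direction, with their adjusted p there: liver 0.477, cardiac muscle 0.878, keratins 0.0119, aryl hydrocarbon receptor 0.379, antioxidant 0.946, circadian 0.656, fatty acid oxidation 0.961, ionocytes 0.407, neurons 0.433, Nrf2 0.950 and steroid 0.875. Among lists called without the term, at PFOS 5 mg/L fatty acid oxidation 0.427, ionocytes 0.562, liver 0.119, phototransduction 0.557, skeletal muscle 0.925, keratins 0.838 and xenobiotic metabolism 0.878 turned, and at PFECHS 5 mg/L exocrine pancreas 0.878, lipoproteins 0.925, skeletal muscle 0.271 and xenobiotic metabolism 0.756. Some lists not called without the term turned and were called with it. At PFOS 5 mg/L this was intestine (lower, 0.00058). At PFECHS 5 mg/L they were intestine (lower, 0.0053), fatty acid oxidation (lower, 0.0076), Nrf2 targets (lower, 0.0268), phototransduction (higher, 0.0282) and neurons (higher, 0.0258). Over all 194 list calls at any concentration, 73 were called in the same direction with the main-axis term, 61 had that direction without a call, and 60 turned, 13 of them called the other way.

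With the compounds compared and the main-axis term together, FBSA 5 mg/L and PFOS minus FBSA at 5 mg/L gave 0 genes (5989 at an unadjusted p under 0.05 for FBSA 5 mg/L), the FBSA trend 1152, PFECHS minus FBSA at 5 mg/L 2 and PFOS minus FBSA at 1 mg/L 1. PFOS gave 1, 4 and 44 at 0.1, 1 and 5 mg/L and 281 in the trend, and the controls 2 (PFECHS and FBSA) and 3 (PFOS and FBSA). At 5 mg/L CYP19A1 turned to -0.28 (PFECHS) and 0.14 (PFOS), CYP1A1 to 0.58 (FBSA) and -0.29 (PFECHS), FABP1 (ENSDARG00000059227) to -0.26 and cyp3a65 to -0.083 (PFECHS) and HMOX1 to -0.86 (PFOS).

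With a correlation estimated for each list camera called 0 lists in each of the 12 concentration contrasts, where the preset value called 194 in all. Fry, which asks whether a list's genes change at all and not whether they change more than other genes, called 2 lists at PFOS 5 mg/L, 3 at FBSA 5 mg/L and 0 in the other 10 contrasts. These were cell cycle (adjusted p = 0.00488) and the thyroid axis (0.0107) for PFOS. For FBSA they were lens (0.00300), cell cycle (0.0107) and endocrine pancreas (0.0241). Of the 194 calls 4 were called by fry, 184 with the replicate block, 187 with the own compound alone, 189 with the table-place term, 168 with the first 33 libraries and 174 with lists matched by the same symbol. With that matching, aryl hydrocarbon receptor (adjusted p = 0.832), complement (0.842), extracellular matrix (0.584) and steroid (0.801) turned at FBSA 5 mg/L.

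Leave-one-out ranges of the counts were 141 (without FBSA 5 mg/L replicate 3) to 5197 (without replicate 2) at FBSA 5 mg/L and 474 to 4561 in the FBSA trend (the same libraries). They were 56 to 4100 in PFOS minus FBSA and 333 to 4917 in PFECHS minus FBSA at 5 mg/L (the same libraries), and 0 to 89 at FBSA 1 mg/L (89 without FBSA 1 mg/L replicate 3). They were 0 to 1 at FBSA 0.1 mg/L, PFOS 0.001 mg/L, PFOS 1 mg/L, PFECHS minus FBSA at 0.1 mg/L and PFOS minus FBSA at 0.001, 0.1 and 1 mg/L. For PFOS they were 0 to 3 at 0.1 mg/L, 0 to 5 at 5 mg/L and 5 (without control replicate 1) to 79 in the trend. The PFOS against FBSA controls ranged from 0 to 271 and the PFECHS against FBSA controls from 0 to 1653. FBSA control replicate 2 is the library without which FBSA 5 mg/L gave 452.

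Correlations ranged with a library left out from -0.59 to 0.061 (PFOS and FBSA, 0.001 mg/L), -0.020 to 0.48 (0.1 mg/L) and -0.25 to 0.13 (1 mg/L), and from -0.38 to 0.067, -0.0055 to 0.46, -0.12 to 0.15 and -0.44 to -0.25 (PFECHS and FBSA, 0.001 to 5 mg/L). PFOS and PFECHS at 0.001 mg/L ranged from 0.17 to 0.59. With genes of mean log2 CPM of at least 3, PFECHS and FBSA at 1 mg/L turned to -0.037. A prior count of 0.5 and removal of the table-place term changed no direction among the 12. Uncalled genes that turned with a library left out ranged from -0.33 to 0.28 (CYP19A1, PFECHS 5 mg/L), -1.14 to 0.20 (CYP19A1, PFOS 5 mg/L), -0.11 to 0.60 (HMOX1, FBSA 5 mg/L), -0.25 to 0.58 (HMOX1, PFOS 5 mg/L), -0.024 to 0.51 (HSP90AA1, FBSA 1 mg/L), -0.028 to 1.25 (c4, PFOS 1 mg/L), -0.078 to 0.14 (PER1 ENSDARG00000012499, PFECHS 5 mg/L), and for PER1 ENSDARG00000056885 from -0.55 to 0.045 (FBSA 5 mg/L) and -0.21 to 0.20 (PFECHS 5 mg/L).

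Of 276 named gene results 146 were called. No called one turned direction under an alternative, 2 kept their call under every alternative and 144 lost it under at least 1.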

Other observations

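The table-place and first-33 tests, the tests of the FBSA 1 mg/L pools, the settings with the main axis and the genes picked here were chosen after seeing the data, and the splits were planned. The few genes called under PFOS are described here across concentrations. They were picked for their values, the concentrations share controls, and no test compares concentrations. COLGALT1 changed by 0.50, 1.23, 1.07 and 1.00 from the lowest to the highest concentration and the helicase subunit GINS3 by -0.37, -0.70, -0.88 and -0.72. RGCC changed by 0.12, 0.35, 0.79 and 1.09. The placeholder gene si:dkey-27m7.4 is near the floor in controls (log2 CPM -2.33, -2.14 and -1.57) and stood at -0.64, -0.67 and -0.63 at 0.001 mg/L and 1.07, 0.25 and 0.91 at 0.1 mg/L. ENSDARG00000110040 went up with PFOS at 1 mg/L by 3.08 ± 0.60 (adjusted p = 0.0640) and stood lower under FBSA at 5 mg/L (-1.76 ± 0.55, adjusted p = 0.0371). Its difference at 5 mg/L, PFOS minus FBSA, was 4.35 (95% interval 2.71 to 5.99, adjusted p = 0.00836), larger than that of PRKG2, and it was left out of the ranking because it has no symbol. The 79 genes of the PFOS trend had no equal among 31 splits of the libraries, the real one included (highest other 0). The smallest share these splits allow is 1 of 31, not adjusted over the results split, so chance is made less likely but not excluded. The count lay between 5 (without control replicate 1) and 79 with a library left out, and the report names each library that moves it.

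Single genes called at FBSA 5 mg/L that the report does not name follow, from lists that were not called. MMP9, a matrix-degrading protease, rose by 1.90 ± 0.61 (adjusted p = 0.0392) and the chemokine receptor CXCR4 (ENSDARG00000057633) by 1.24 ± 0.40 (adjusted p = 0.0440). The kidney salt transporter SLC12A1 changed by -2.37 ± 0.68 (adjusted p = 0.0242), the carbonic anhydrase ca2 by -1.20 ± 0.29 (adjusted p = 0.00879) and the steroid reductase SRD5A1 by -1.11 ± 0.33 (adjusted p = 0.0290). They share the limits of the FBSA count: no gene was called by edgeR with the FBSA libraries alone (0, against 3548 at an unadjusted p under 0.05, and 3505 by DESeq2 in the fit of all libraries).

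The main axis between libraries, 29.2% of the variance, places most members of many tissue lists on the same side by the sign of their loadings. No enrichment was tested, and lists that mark no tissue lean as well, such as Nrf2 targets (21 of 25 positive). All 39 extracellular matrix genes, 38 keratins, 35 liver genes and 44 lens genes lie on its positive side with 25 of 26 exocrine pancreas and 34 of 36 intestine genes, and 44 of 46 phototransduction, 74 of 76 ribosomal and 28 of 32 circadian genes on the negative side. Cell cycle genes split 22 and 25. A difference in stage or hatching between pools at collection may lie behind it, which no label records and no test here addressed, and with the axis as a term the FBSA 5 mg/L genes had a median ratio of 0.870. The same axis was found in the PFOS and PFECHS libraries alone (24.5% of their variance, correlation of the axes 0.977). For FBSA at 0.001 mg/L the real split called 0 genes by edgeR (259 at an unadjusted p under 0.05, 0 by DESeq2), while the split of control replicates 1 and 2 and exposed replicate 1 against the rest called 8551 and follows the axis, a structure of the samples. In PFOS minus FBSA and PFECHS minus FBSA at 0.001 mg/L the real counts were 0 and the highest others 889 and 5599, with FBSA libraries parted the same way.

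Cell cycle genes under PFOS at 5 mg/L were lower by a median of -0.397 in mean log2 CPM. With table place as a term the median was -0.406 (-0.442 to -0.385 with a library left out) and with the main axis -0.363 (-0.425 to -0.326), where a cause would have brought it below 0.5 of its size. That argues against both as the whole cause. A correlation between the genes of the list stays open, since camera with an estimated correlation gave an adjusted p = 0.0954 and fry 0.00488. Slower cell division under PFOS is a hypothesis from the exposure groups, found and tested on the same data.

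The 3 pools at FBSA 1 mg/L differ in how far they go toward the 5 mg/L change, with scores of 0.593, 0.502 and 0.228 on a scale where the controls average 0 and the 5 mg/L pools 1 (0.814, 0.765 and 1.42; controls 0.00412, -0.212 and 0.208). The scores use the genes called at 5 mg/L and share the controls. A swap of replicate 3 with a lower pool could explain its low score, but the lower of the other scores lies 0.210 above the highest lower pool (0.292), less than the 0.419 range of the controls, so the swap cannot be told apart from spread between pools. A bound used first, the lowest 5 mg/L score of 0.765, was reached by no lower pool and was replaced, since a pool of 1 mg/L need not reach it. Table place cannot be told apart either: replicates 2 and 3, both late in the table, differ by 0.274, and replicate 1 lies 0.228 above their mean, both within the control range.

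The last 11 libraries of the table stand apart on component 2 (24.7 to 58.7 against at most 21.3). Their share of values that are not whole is higher in the median (75.8% against 66.8%), with ranges that overlap (71.7% to 79.8% against 54.1% to 73.7%). With groups in the fit 6675 genes differed, 2996 higher and 3679 lower in the last 11, which may come from a later sequencing run. The labels give no run, so this place served as a term, with a ratio of 0.894 for the FBSA 5 mg/L genes. No biological explanation was tested for it, and all 3 pools of FBSA at 5 mg/L are among the first 33 while 2 of their 3 controls are among the last 11.

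For the other comparisons of 3 against 3 libraries 10 splits are too few for a share under 0.05. The real counts and the highest others were 0 and 0 for PFOS at 0.001 mg/L, 4 and 0 at 0.1, 2 and 0 at 1, and 3 and 0 at 5 mg/L. For PFECHS they were 0 and 0 at 0.001, 0 and 1 at 0.1 and 0 and 0 at 1 and 5 mg/L, and for FBSA at 1 mg/L 0 and 12, a count above the real one. For controls they were 34 and 0 (PFOS and FBSA), 0 and 0 (PFOS and PFECHS) and 0 and 0 (PFECHS and FBSA). Where the real count is 0 every split gives as many, so the number of splits says nothing about chance. This holds for the PFECHS trend (31 of 31, highest other 0), for PFOS minus PFECHS at each concentration (25 of 25, highest other 0) and for PFOS minus FBSA and PFECHS minus FBSA at 0.001 and 1 mg/L (25 of 25, highest other at 1 mg/L 1 and 3). The edgeR counts of 0 named here stand in the report beside their unadjusted and DESeq2 counts. FBSA at 0.1 mg/L has 2 libraries, so splits were not run for it or for the FBSA trend.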
